A study of Leishmania major with 6 samples.

How the data were processed

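RNA was measured in 6 cultures of *Leishmania major* promastigotes, the flagellated form of the parasite that lives in the sand fly and grows in culture medium. Per the labels, 3 cultures were controls (given saline, and called untreated in the description of the series) and 3 were exposed to EPHB for 24 h at a dose labelled 3.22 µm, with the unit as labelled. EPHB is known here only by its code name. The labels number the samples of each group as biological replicates 1 to 3 and do not say how the cultures were separated, so p-values measure the spread between these samples. Per the labels' protocols, total RNA was turned into stranded mRNA libraries and sequenced as paired ends.

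Per the submitters' processing notes, the reads were handled with FastQC, TopHat and featureCounts. Versions, options and the genome build are not given in the sources used here, nor is it stated whether strand was used in counting or how reads that match several genes were treated. Each deposited file holds 1 library with 9388 genes, and the columns carry the names featureCounts gives them, per the file headers. The file names speak of TPM, but the deposited values are CPM made by the authors. Each library sums to 1000000, and 100% of its non-zero values are whole multiples of 1 step, within a tolerance of 0.01 of a read, whatever the length of the gene. The step is the worth of 1 read, so whole reads were recovered for every gene. The totals were 2574305, 2744258 and 2477152 reads in control replicates 1, 2 and 3 and 3207815, 3001474 and 4228977 reads in EPHB replicates 1, 2 and 3. One read was worth between 0.236 and 0.404 CPM, so a gene at 1 CPM rests on a few reads.

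Gene IDs were matched to an annotation table of the assembly ASM272v2 (*L. major* strain Friedlin). All 9388 matched, with equal start and end in the files and the table, and coordinates are given as in the files. The table gives symbols but no product descriptions, and 465 of 8316 protein-coding genes have a symbol. Of the protein-coding genes, 99.9% have a length divisible by 3, so the lengths are coding lengths and the models hold no untranslated regions. Genes without a symbol are called by their ID.

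The test had been fixed before the data were examined, for files expected to hold TPM or counts. It was edgeR (quasi-likelihood) if the files held read counts, and limma-trend on log2(TPM + 1) otherwise. As the values are CPM, limma-trend was run on log2(CPM + 1) over genes with at least 1 CPM in at least 3 libraries, with the group as the only term, in R 4.3.3 with limma 3.58.1. This left 8051 genes, of which 7907 code for protein and 382 of these have a symbol. P-values were two-sided, adjusted by the Benjamini-Hochberg method, and called under 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. On simulated reads with 100 genes changed 2-fold and 100 changed 4-fold, over 8040 genes, this test of EPHB against control recovered 53% and 87% of them with 0 false calls. The changed genes were drawn from those with a mean of at least 10 CPM. The simulated reads held the difference of the pair of libraries that stand apart, but no other trend of a single library.

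Gene lists were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists with at least 5 tested members, beside camera with an estimated correlation and fry. The topics of most lists had been fixed beforehand as patterns for product descriptions. Since the annotation gives none, members were assigned by symbol after the annotation was seen and before any gene was tested. The lists of lipophosphoglycan synthesis, pteridine and folate metabolism, GPI anchor and N-glycan assembly, purine salvage and spliced leader RNA were added at that step. Tested were 18 lists. Lists with fewer than 5 tested members were GP63 leishmanolysins (3), metacyclic promastigote markers (2), tRNA (4), rRNA (2) and spliced leader RNA (0), and they were not tested. Lists planned for polyamine, sterol, proteasome, respiratory chain, citric acid cycle, flagellum, tubulin, amastin, surface antigen, histone, cysteine peptidase, aminoacyl-tRNA synthetase, vesicle traffic and ribosome assembly genes had no member set by symbol and give no result. Each of the 36 chromosomes was tested as a set in the same way.

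Genes named in the text follow a rule fixed beforehand. With fewer than 5 genes past the threshold, these are the 10 genes with a symbol and the smallest p, up to 4 members of each list with the smallest p, and a fixed set of drug-related genes, of which TRYR, TRYS, PTR1, AQP1 and MCA5 are reported. Genes named from the 4 libraries described in the report, and all genes named by ID, were chosen after their values were seen.

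Alternatives fixed beforehand were quantile normalization, TMM-like scaling of CPM, other filters and pseudocounts, a replicate block, other thresholds and leaving out each library in turn. Added after the data were seen were a term for a pair of libraries that stand apart, a fit without that pair, a lowess correction (span 0.3) of each library for coding length, and count tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

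Whether reads shared between gene copies affect the values was not tested, as no sequence was used here. Of 17 genes named HSP83, 16 are listed at 0 in every library and HSP83-17 lay at 7.01 ± 3.61 CPM (SD, n = 3) in control and 8.87 ± 2.13 CPM in EPHB. In all, 338 protein-coding genes are listed at 0 in every library. The same question is open for other families of genes with like names, such as AAT1, ELO, KMPII, GP63 and EIF5A.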

Results

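The transcriptome of *Leishmania major* promastigotes was compared between 3 control cultures and 3 cultures exposed to EPHB for 24 h, to ask how this compound with reported activity against the parasite acts on gene expression. Between 2477152 and 4228977 reads per library were counted in genes, and 8051 genes were tested. Values are CPM, given as mean ± SD (n = 3) unless stated.

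No gene passed the test between EPHB and control. The gene with a symbol and the smallest p was PABP1, a poly(A)-binding protein that binds the tails of mRNA (LMJF_35_5040, chromosome 35, 1969384 to 1971066, plus strand). It measured 774 ± 126 CPM in control and 423 ± 129 CPM in EPHB, a log2 fold change of -0.90 ± 0.23 (SE), and all 3 EPHB libraries lay below all 3 controls. EIF5A1, which encodes a translation factor (LMJF_25_0720, chromosome 25, 269321 to 269821), measured 424 ± 50.2 CPM in control and 300.5 ± 19.1 CPM in EPHB (log2 fold change -0.49 ± 0.13). ALDH2, an aldehyde dehydrogenase gene (LMJF_25_1120, chromosome 25, 452597 to 454096), measured 89.7 ± 9.57 CPM in control and 128 ± 9.93 CPM in EPHB (log2 fold change 0.51 ± 0.14). With limma, the adjusted p of each of these genes was 0.999.

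The remaining genes among the 10 with a symbol and the smallest p did not pass either. Lower in EPHB by their means were RPL10a, a ribosomal protein gene (880.3 ± 108 against 664 ± 10.2 CPM, log2 fold change -0.40), CYP2, a cyclophilin (849 ± 58.0 against 668 ± 29.7 CPM, -0.34), and AAT1.4, an amino acid transporter (3961 ± 939.6 against 2309.8 ± 946 CPM, -0.83, with overlapping groups). Higher by their means were LmISP3, an inhibitor of serine peptidases (138 ± 10.2 against 181 ± 9.99 CPM, 0.39), INO1, the synthase that makes inositol phosphate (310.3 ± 25.9 against 385 ± 24.0 CPM, 0.31), and PEX13, a peroxin of the glycosome membrane (112 ± 8.87 against 136 ± 4.49 CPM, 0.29). SCG3, a glycosyltransferase of lipophosphoglycan side chains, rested on 3 reads over the 3 control libraries and 21 over the 3 EPHB libraries, a ratio of 5.23 with an exact 95% counting interval of 1.56 to 27.4. The interval covers counting error only.

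**Figure D1:**
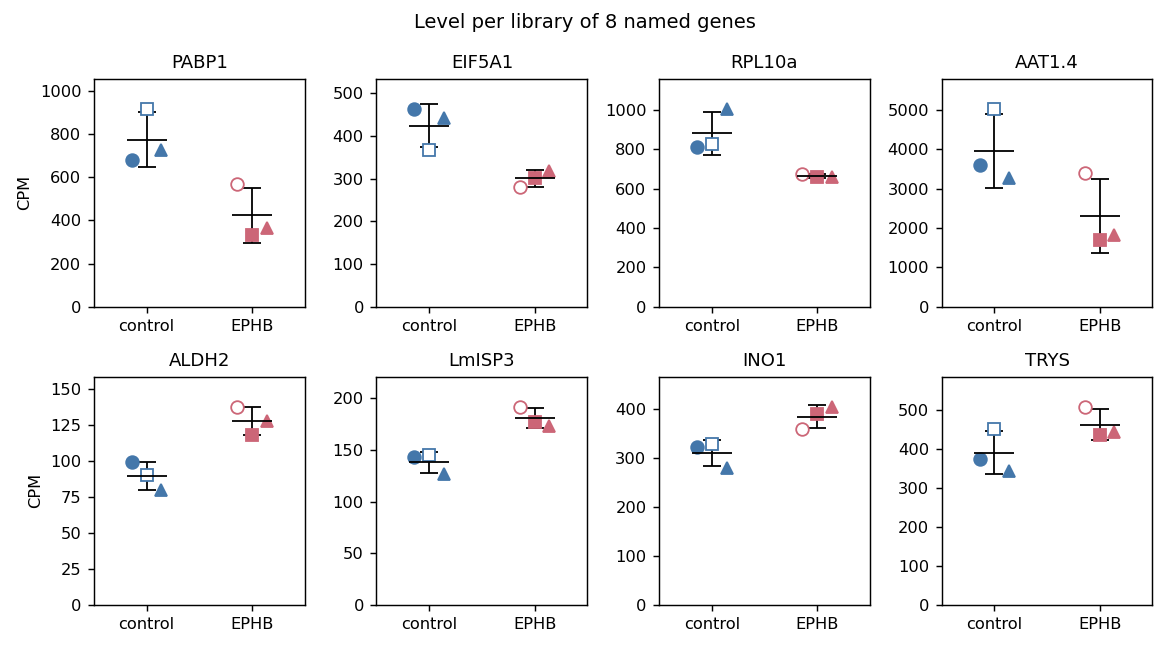
CPM of 8 genes in each library (vertical axes from 0), with control in blue, EPHB in red, circles, squares and triangles for replicates 1, 2 and 3, open symbols for control replicate 2 and EPHB replicate 1, and bars for the mean and SD (n = 3). PABP1 lay at 774 ± 126 CPM in control and 423 ± 129 CPM in EPHB, and ALDH2 at 89.7 ± 9.57 and 128 ± 9.93 CPM.

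Of the fixed drug-related genes reported here, none passed the test. TRYS, which makes the thiol trypanothione, measured 390.1 ± 55.3 CPM in control and 463 ± 40.4 CPM in EPHB (log2 fold change 0.25). TRYR, which keeps trypanothione reduced, measured 879.8 ± 36.6 and 916 ± 112 CPM (0.05). PTR1, the pteridine reductase, measured 121 ± 12.2 and 117 ± 25.01 CPM (-0.06). AQP1, an aquaglyceroporin that takes up antimonials, measured 20.1 ± 2.70 and 25.3 ± 1.05 CPM (0.33). MCA5, a metacaspase, measured 101 ± 4.59 and 103 ± 8.92 CPM (0.02). The sign of TRYR turned under TMM-like scaling, and that of MCA5 under TMM-like scaling and quantile normalization. PTR1 turned to 0.02 without control replicate 1, 0.12 without EPHB replicate 1 and 0.08 in the 4 libraries.

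By limma, 156 genes had an unadjusted p under 0.05 where 402.55 were expected by chance, and the smallest adjusted p was 0.999. edgeR on the recovered reads also called 0 genes, with 142 at an unadjusted p under 0.05, and DESeq2 called 0, with 165. Values of the 3 EPHB libraries did not overlap those of the 3 controls in 621 genes, 7.71% of those tested, where chance gives 10%. Of these, 432 were higher and 189 lower in EPHB, and under TMM-like scaling 260 and 338. The 95% interval of a log2 fold change reached 0.44 to either side of its estimate at the median gene.

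Control replicate 2 and EPHB replicate 1 stood apart from the other 4 libraries. The first principal component held 70.6% of the variance and separated them, and their log2 values correlated at 0.983 with each other, against a median of 0.930 with the other 4. With the group in the model, 3884 genes differed between this pair and the rest, of which 2304 were higher in the pair. The difference went with gene length: the median CPM of genes over 4000 nt was 1.80 times that of genes under 500 nt in control replicate 2 and 2.08 times in EPHB replicate 1, against 0.925 to 1.03 in the other 4. As the pair holds 1 library of each group, fits with a term for it and without it were added after the data were seen.

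**Figure D2:**
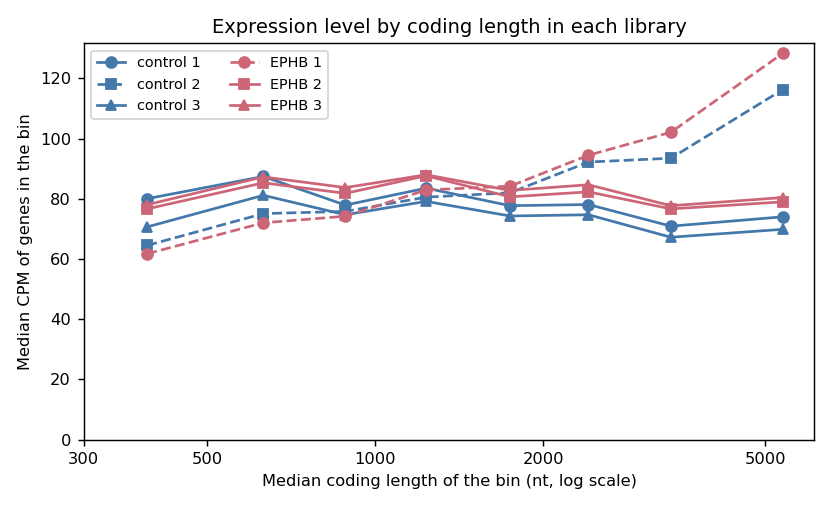
Median CPM (vertical axis, from 0) of protein-coding genes in 8 bins of coding length (horizontal axis, nt, log scale), one line per library, with control in blue and EPHB in red. The dashed lines of control replicate 2 and EPHB replicate 1 reached 116 and 128 CPM in genes over 4000 nt, and the other 4 libraries lay between 69.8 and 80.4 CPM there.

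With the term for the pair, PABP1 fell under EPHB (log2 fold change -0.90 ± 0.098, limma adjusted p = 0.00038) and was the 1 gene called, with 1377 at an unadjusted p under 0.05. EIF5A1 reached an adjusted p of 0.068 in this fit. Over all alternatives run, with limma, edgeR or DESeq2, the adjusted p ranged from 1.8e-14 to 1 for PABP1 and from 1.54e-05 to 1 for EIF5A1, and both were lower in EPHB in each. In the simulation, the fit with the term recovered all genes changed 2-fold and 4-fold, with 11 false calls. The simulated reads were built with the same term, so this does not show that the term is right for the real libraries. edgeR with the same term called 3 genes, all lower: PABP1 (adjusted p = 0.00098), EIF5A1 (adjusted p = 0.040) and LMJF_31_0900 (adjusted p = 0.0081), a gene with no symbol at 156 ± 33.8 CPM in control and 98.0 ± 13.8 CPM in EPHB.

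In the 4 libraries without the pair (control replicates 1 and 3, EPHB replicates 2 and 3), limma called 375 genes, of which 294 rose and 81 fell. Under TMM-like scaling the split was 111 up and 139 down, and 190 of those genes were among the 375. EPHB replicates 2 and 3 correlated at 0.992 with each other (log2 values), and control replicates 1 and 3 at 0.983. Genes with a symbol among the 375 numbered 27, with 8 up and 19 down. Among those that fell were 5 amino acid transporters. AAT1.4 went from 3427 ± 232 to 1765 ± 89.5 CPM (SD, n = 2), AAT16 from 1187 ± 49.5 to 716 ± 5.02, AAT19 from 966 ± 222 to 617 ± 14.5, AAT1.1 from 389.7 ± 52.1 to 264 ± 7.63 and AAT27.2 from 101 ± 2.29 to 71.9 ± 2.69. PABP1 went from 702 ± 30.6 to 349 ± 21.2 CPM, KMPII-1, a kinetoplastid membrane protein, from 373 ± 69.7 to 261 ± 9.50, and ELO2, a fatty acid elongase, from 198 ± 32.1 to 136 ± 3.53. Also lower were PKAC1, a catalytic subunit of protein kinase A (log2 fold change -0.44), CRK3, a kinase of the cell cycle (-0.41), TRYP3, a tryparedoxin peroxidase (-0.34), and the cyclophilin CYP4 (-0.47).

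Genes with a symbol called higher in these 4 libraries included GP63-1, a surface metallopeptidase (3.53 ± 2.14 to 10.6 ± 1.36 CPM, n = 2), CYP16, a cyclophilin (67.4 ± 7.99 to 93.4 ± 5.02 CPM), ALDH2 (89.5 ± 13.5 to 123 ± 6.73 CPM) and INO1 (301 ± 29.3 to 398 ± 10.2 CPM). PUF4, a Pumilio-family RNA-binding protein, had a log2 fold change of 0.42 and the ABC transporter ABCA10 one of 0.34. Limma's adjusted p of the genes named from the 4 libraries lay between 0.00032 and 0.048. Other scalings of the same 4 libraries ended the calls of CYP16, ALDH2, INO1, PUF4 and ABCA10, with adjusted p from 0.068 to 0.146 by limma under TMM-like scaling and from 0.0534 to 0.135 by edgeR. GP63-1 passed in both, but control replicate 2, left out here, lay at 19.3 CPM, above every EPHB library (9.66 to 18.7 CPM). Its call rests on few control reads: control replicates 1 and 3 lay at 5.05 and 2.02 CPM, where 1 read was worth 0.388 and 0.404 CPM. Of genes without a symbol, LMJF_34_1170 (log2 fold change 0.53) and LMJF_31_2230 (0.67) rose and LMJF_32_2620 (-0.43) fell. In the pair left out, the log2 difference of EPHB replicate 1 from control replicate 2 was -0.68 for PABP1, -0.56 for AAT1.4, -0.34 for AAT16 and 0.61 for ALDH2, but -0.04 for GP63-1, 0.02 for AAT1.1, 0.17 for PKAC1 and 0.11 for CRK3. PABP1, AAT1.4 and ALDH2 had been picked by their p over all 6 libraries, so the pair is no independent check of them.

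The gene lists asked whether genes of a known function differed together. Of 18 lists, 5 were lower in EPHB relative to all other genes by camera, with 0 higher. They were membrane transporters (adjusted p = 0.020), fatty acid and phospholipid metabolism (0.020), heat shock proteins and chaperones (0.035), cytosolic ribosomal proteins (0.035) and protein kinases (0.035). With an estimated correlation, none of the 5 passed (adjusted p = 0.779 for each). Fry asks another question, whether the genes of a list move one way on balance, without comparing them with other genes, and gave an adjusted p of 0.976 for each. Without control replicate 1 the count of lists was 0, without control replicate 2 it was 1, and after the correction for coding length it was 0. After that correction the medians of the 5 lists still lay below that of all genes, with differences from -0.12 to -0.08, against -0.17 to -0.09 before.

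Among membrane transporters, 16 of 30 tested members were lower by their means and 14 higher, with a median log2 fold change of -0.04 against 0.08 over all genes. The median turned to 0.06 without control replicate 2. Adjusted over the list alone, 0 members passed, and with the term for the pair 5, all lower. AAT8.2 measured 167 ± 19.8 CPM in control and 136 ± 20.7 CPM in EPHB, and AAT27.2 measured 92.3 ± 15.0 and 74.0 ± 4.14 CPM. Of 16 genes of fatty acid and phospholipid metabolism, mostly elongases, 12 were lower by their means (median -0.09). Their median was -0.05 without control replicate 1, -0.05 without control replicate 2 and -0.17 in the 4 libraries. ELO2 measured 216 ± 39.7 and 168 ± 54.8 CPM, and ELO3.2 33.8 ± 12.4 and 21.4 ± 12.8 CPM. Adjusted over the list alone, 0 passed without and 2 with the term for the pair, both lower.

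The list of heat shock proteins and chaperones held mostly cyclophilins, which are peptidyl-prolyl isomerases, and 12 of its 20 members were lower by their means (median -0.01, and 0.02 without control replicate 1). CYPA measured 1043 ± 38.6 and 899.8 ± 83.1 CPM, and CYP16 went the other way, at 69.6 ± 6.80 and 88.1 ± 9.78 CPM. Of 9 cytosolic ribosomal proteins, 5 were lower (median -0.05), among them RPL11 at 1408 ± 439.7 and 1077 ± 109 CPM. Its log2 fold change was -0.35 with all libraries and -0.11 without control replicate 3, which lay at 1916 CPM. Their median turned to 0.05 under quantile normalization and to 0.04 in the 4 libraries. Of 16 protein kinases, 8 were lower and 8 higher, with a median of -0.01 and a mean of 0.01, and the median was -0.09 without control replicate 1 and -0.09 in the 4 libraries. MKK, a MAP kinase kinase, measured 371 ± 14.4 and 322 ± 32.5 CPM. Adjusted over the list alone, 0 members of each of these 3 lists passed, and with the term for the pair 1 ribosomal protein, lower.

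**Figure D3:**
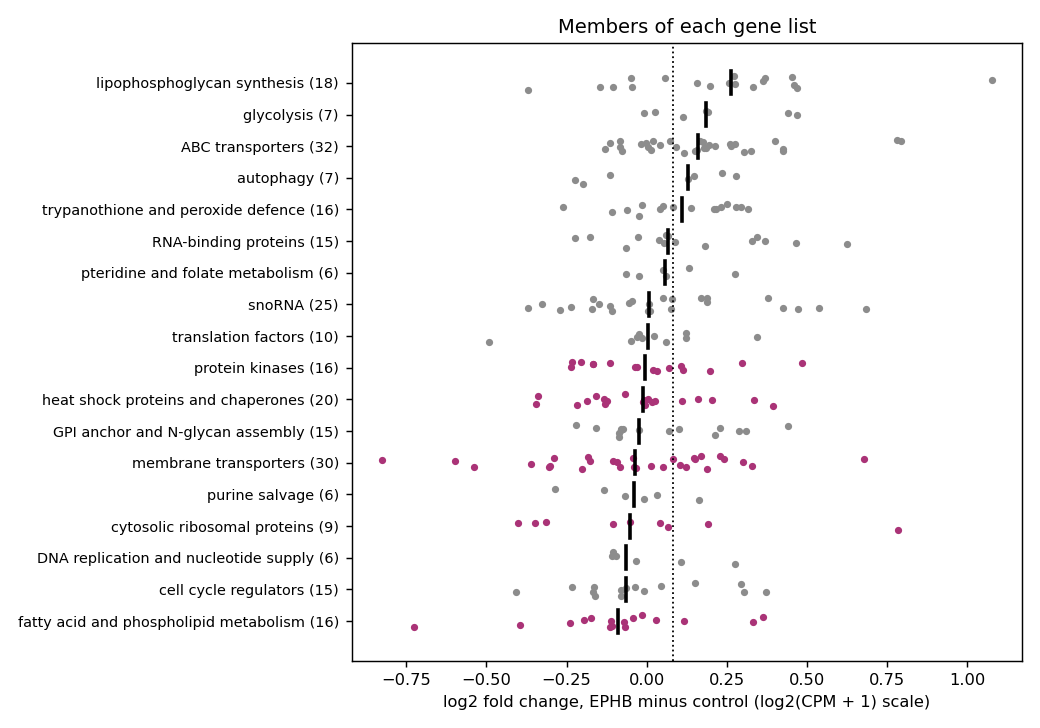
Log2 fold change of EPHB against control (horizontal axis, log2(CPM + 1) scale) for each tested member of 18 gene lists, with the number of members in brackets, points for genes, black bars for list medians and a dotted line for the median of all genes (0.08). The 5 lists in purple had a camera adjusted p under 0.05 with the preset correlation and none with an estimated one.

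The other 13 lists did not pass by camera, but under quantile normalization glycolysis passed as higher (median 0.28, adjusted p = 0.000669, and up to 0.750026 under the other settings with the preset correlation). With an estimated correlation its camera adjusted p was 0.237 under quantile normalization and 0.779 without it. Of all genes tested, 69.0% were higher in EPHB with the group alone and 52.7% under TMM-like scaling. The counts of members that follow are to be read against the 69.0%. Higher by their means were 11 of 16 members of trypanothione and peroxide defence (median log2 fold change 0.11), 25 of 32 ABC transporters (0.16), 6 of 7 glycolytic genes (0.19), 13 of 18 genes of lipophosphoglycan synthesis (0.26), 11 of 15 RNA-binding proteins (0.07), 4 of 7 autophagy genes (0.13), 4 of 6 genes of pteridine and folate metabolism (0.06) and 14 of 25 snoRNAs (0.01), with medians below 0 under TMM-like scaling for RNA-binding proteins, pteridine and folate metabolism and snoRNAs, and under quantile normalization for snoRNAs. Within them, TDR1, a thiol-dependent reductase, measured 94.2 ± 11.7 and 118 ± 15.5 CPM, FESODA, an iron superoxide dismutase, 186 ± 28.1 and 225 ± 20.9 CPM, and TRYP3 377 ± 19.97 and 314 ± 14.1 CPM. The median of ABC transporters was 0.02 after the length correction and 0.36 without control replicate 2. Without that library the median was 0.21 for RNA-binding proteins, 0.23 for snoRNAs and 0.18 for trypanothione and peroxide defence. It was 0.08 for autophagy and 0.04 for pteridine and folate metabolism, against 0.11 over all genes. The phosphoglycerate mutase PGAM measured 384 ± 23.5 and 437 ± 32.5 CPM, SCG5 219.9 ± 16.6 and 263 ± 10.2 CPM and PUF10 242 ± 18.0 and 207 ± 15.6 CPM.

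Lower by their means were 10 of 15 cell cycle regulators (median -0.06), 4 of 6 genes of DNA replication and nucleotide supply (-0.06), 4 of 6 genes of purine salvage (-0.04) and 8 of 15 genes of GPI anchor and N-glycan assembly (-0.02). Translation factors split into 5 and 5 (0.00, and -0.06 under TMM-like scaling). The medians of DNA replication and cell cycle genes turned positive without control replicate 2, and those of GPI anchor and purine salvage genes without control replicate 1. HGPRT of purine salvage measured 464 ± 36.8 CPM in control and 381 ± 46.8 CPM in EPHB. PMI, phosphomannose isomerase, measured 68.3 ± 13.5 and 93.0 ± 19.0 CPM. Camera's direction was lower for the autophagy, snoRNA, translation factor and RNA-binding lists, whose medians and means were above 0. The lists of DNA replication and of GPI anchor assembly had medians below 0, means above 0 and camera's direction lower. Cell cycle regulators passed by camera in the 4 libraries (adjusted p = 0.00924, and up to 0.318 under the other settings with the preset correlation), but not with an estimated correlation (adjusted p = 0.832). Adjusted over the list alone, 0 members of the 13 lists passed in the test with the group alone. With the term for the pair, 3 RNA-binding proteins and 2 GPI anchor and N-glycan genes passed as higher, and so did 1 gene each of the ABC transporter, glycolysis, DNA replication and pteridine lists. In that fit 1 translation factor and 1 purine salvage gene passed as lower.

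Chromosomes were tested because whole chromosomes can differ in copy number between *Leishmania* cultures. None of the 36 passed by camera in all 6 libraries (smallest adjusted p = 0.064, for chromosomes 2, 12 and 36). The median log2 fold change was 0.19 on chromosome 2, 0.15 on chromosome 12, 0.04 on chromosome 35 and 0.03 on chromosome 36. In the 4 libraries, 7 chromosomes passed, with 5 higher and 2 lower (35 and 36) relative to other genes, and without control replicate 2, 6 passed. Control replicate 1, 1 of the controls in both fits, had medians of -0.15 on chromosomes 1 and 2, 0.04 on chromosome 35 and 0.05 on chromosome 36 relative to the mean of the 6 libraries. With an estimated correlation none passed in the 4 libraries (adjusted p = 0.971).

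**Figure D4:**
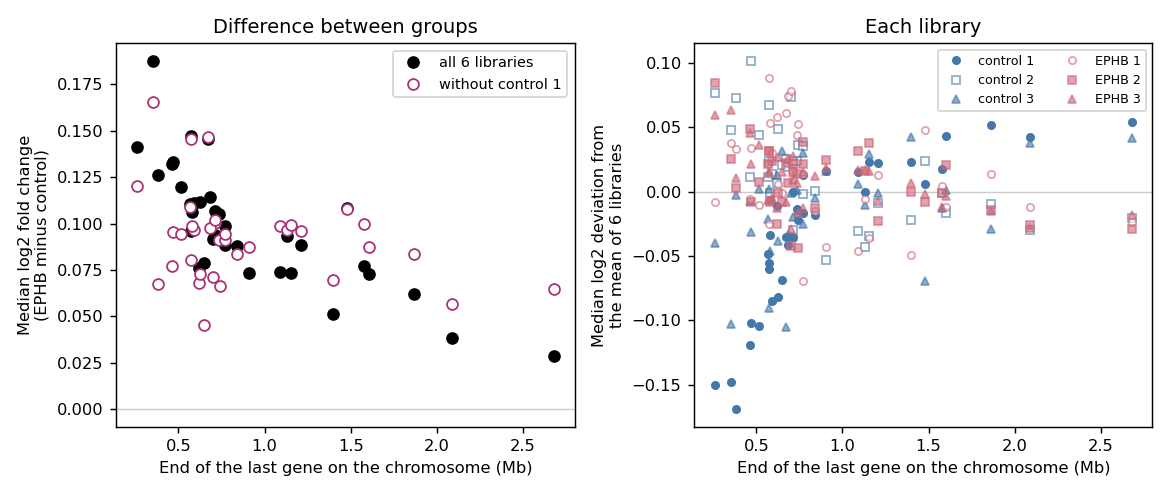
Median log2 values of each of the 36 chromosomes against the end of its last gene (horizontal axes, Mb): on the left the difference of EPHB from control with all 6 libraries (black) and without control replicate 1 (open), and on the right the deviation of each library from the mean of the 6, with control in blue, EPHB in red and open symbols for control replicate 2 and EPHB replicate 1. In control replicate 1 the 5 smallest chromosomes averaged -0.14 and the 5 largest 0.04.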

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

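The fits with a term for the pair of libraries that stand apart, without that pair, with a correction for coding length and on recovered reads, quantile normalization with an estimated correlation, and TMM-like scaling for lists and chromosomes, were chosen after seeing the data. The count of 0 genes was the same under quantile normalization, TMM-like scaling, other filters, pseudocounts and thresholds, without each library in turn (range 0 to 0), after the length correction and with edgeR and DESeq2 with the group alone. It became 1 with the term for the pair, 3 with the term and TMM-like scaling, 3 with the term in edgeR, 88 with the term in DESeq2 (2 higher, 86 lower), 375 without the pair, 250 without it under TMM-like scaling, and 381 without it in edgeR (170 higher, 211 lower). Of the calls without the pair, 37 were among the 88 and 248 among the 381.

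Lists called went from 5 to 1 under quantile normalization (glycolysis, higher), 2 under TMM-like scaling, 3 with the term for the pair, and 0 after the length correction and with an estimated correlation (alone, with the term and under quantile normalization). Fry, which does not compare a list with other genes, called 0. After the length correction all 5 still lay below the median of all genes, by -0.12 to -0.08 against -0.17 to -0.09 before, and why the calls ended was not tested. Leaving out 1 library gave 0 to 4, with 0 without control replicate 1, 1 without control replicate 2, 2 without EPHB replicate 2 and 2 without EPHB replicate 3. Chromosomes called went from 0 to 1 under quantile normalization, 3 under TMM-like scaling and 7 without the pair, and leaving out 1 library gave 0 to 6, with 6 without control replicate 2. Apart from the pair, the cause was not tested.

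Deviations from the group means correlated at -0.60, -0.74 and 0.52 between the same-numbered samples 1, 2 and 3. Both negative values involve a library of the pair that stands apart. Differently numbered couples of control and EPHB outside that pair gave 0.54 to 0.58. These values therefore cannot tell whether the numbers pair the samples. With a replicate block, 0 genes, 6 lists (the 5 and cell cycle regulators) and 1 chromosome passed. EPHB replicate 1 correlated best with control replicate 2.

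Of the genes named, 5 turned sign under some setting, and the cause was not tested. TRYR (0.05) turned to -0.0207 under TMM-like scaling with and without the term, -0.0263 after the length correction, -0.0131 in edgeR (-0.0144 with DESeq2 size factors, -0.0127 with no filter), -0.0142 in DESeq2, and -0.0202 and -0.0209 with the term in edgeR and DESeq2. MCA5 (0.02) turned to -0.0403 under quantile normalization, -0.0477 under TMM-like scaling with and without the term, -0.0461 after the length correction, -0.0516 without the pair, -0.0492 in edgeR (-0.0500045 with DESeq2 size factors, -0.0490 with no filter) and DESeq2, -0.0472 and -0.0493 with the term in edgeR and DESeq2, and -0.139 and -0.138 without the pair under TMM-like scaling and in edgeR. PTR1 (-0.06) turned to 0.0820 without the pair. Leaving out 1 library gave TRYR -0.00539 to 0.157, PTR1 -0.176 to 0.124, MCA5 -0.0455 to 0.0680, PUF4 -0.0360 to 0.784 and ABCA10 -0.00636 to 0.774, the lowest of PUF4 and ABCA10 without EPHB replicate 1. Depth limits genes near 1 CPM, such as SCG3.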

Other observations

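Tests below that were chosen after the result was seen are those of depth, exchanged labels, the side of the pair, control replicate 1 and the other libraries left out over chromosomes, the length trend over chromosomes and the sums over genes that share a name.

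Some genes that stood out share a name with others, and were summed. EIF5A1 and EIF5A2 together measured 515 ± 51.1 CPM in control and 399.6 ± 26.7 CPM in EPHB (SD, n = 3), a log2 difference of -0.36 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). EIF5A2 alone measured 90.4 ± 1.08 and 99.1 ± 13.9 CPM. The 4 AAT1 genes together measured 4380.1 ± 976 and 2649 ± 1056 CPM (log2 difference -0.77, exact permutation p = 0.2). The share of rRNA was 0.0408% in control replicate 3 and 0.0052% to 0.00722% in the other 5 libraries, and LMJF_35_0240, the gene with the highest value in every library, lay at 14237 CPM there and at 4469 to 8435 CPM in the others.

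Control replicate 2 and EPHB replicate 1 differed from the other 4 libraries in 3884 genes. A trend with coding length was not the whole of it, since 62.2% of these genes still differed after each library was corrected for length. Depth was not outside the range of the other 4 in either library of the pair (0 libraries). An exchange of their labels would not by itself set them apart from both groups, since the best correlation with the group each would move to was 0.947, below the lowest among the other 4, 0.978. Whether the labels were exchanged as well stays open. Control replicate 2 correlated at 0.947 and 0.939 with EPHB replicates 3 and 2 and at 0.939 and 0.938 with the other controls, and EPHB replicate 1 at 0.922 and 0.912 with EPHB replicates 3 and 2 and at 0.912 with both other controls. The pair's differences ran as labelled for PABP1 (-0.68) and ALDH2 (0.61). Both were picked over all 6 libraries and had groups that do not overlap, so their sign in the pair was fixed beforehand. It says nothing on the labels. Of the genes called lower without the pair, 64.2% also ran as labelled. Of these lower genes, 75.3% lay below the pair's median, but 1 library per group excludes nothing. As the pair holds 1 library of each group, the EPHB exposure alone would not set it apart. A batch of cultures or of library preparation stays open and untested, since the labels give no batch.

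The genes called without the pair may hold an EPHB effect hidden by the pair's distance from the rest. Among the 81 called lower, 75.3% lay below the median in EPHB replicate 1 minus control replicate 2 (95% exact interval 64.5% to 84.2%), libraries that took no part in the call. After the length correction of that difference 66.7% did, with a wider reach downward (interval 55.3% to 76.8%). Among the 294 called higher, 46.9% lay above it (41.1% to 52.8%), so the pair gave the higher calls no backing on this measure, though 1 library per group cannot exclude them. Without centring on the median, 64.2% of the lower calls and 55.4% of the higher calls had the same sign in the pair, against 54.5% of all genes. The intervals treat genes as independent, which they are not. Of the 3 splits of these 4 libraries into 2 and 2, 1 gave as many genes, the real one with 375, and the highest other gave 0, but 3 splits are too few for a share under 0.05. EPHB replicates 2 and 3 were nearly as close as sampling noise allows, with a chi-square of 1.58 per degree of freedom between their reads. Control replicates 1 and 3 gave 5.92. With EPHB replicates 2 and 3, control replicate 1 gave 5.15 and 5.62, and control replicate 3 gave 8.52 and 10.4. Both other splits separate EPHB replicates 2 and 3. Whether their closeness adds to the calls was not tested.

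The difference between EPHB and control fell with chromosome size (Spearman's rho -0.82 and Pearson's r -0.82 with log2 size over 36 chromosomes, permutation p of rho = 1e-05, the smallest they can give, Benjamini-Hochberg adjusted 2.67e-05 over 8 relations, rho -0.78 without the 2 chromosomes farthest from the median size). The permutations shuffled chromosomes and not cultures, so their p-values do not test EPHB against control. Relative to the mean of all libraries, every single library also gave an adjusted permutation p under 0.05. These ran from 2.67e-05 (control replicates 1 and 2) to 0.0312 (EPHB replicate 2). The mean of all libraries includes control replicate 1, so a trend in that library pushes the others the opposite way. The fall of the EPHB difference with size may depend on control replicate 1. Its rho was -0.22 without that library (permutation p = 0.192) and between -0.77 and -0.61 without any other one. Within control replicate 1 rho was 0.94. Relative to the mean of the other 5 libraries, EPHB replicates 1, 2 and 3 no longer passed, with rho of -0.11, -0.05 and -0.07 (adjusted permutation p = 0.791 for each). On that measure, control replicates 2 and 3 held trends of their own in opposite directions, with rho of -0.57 and 0.57 (Benjamini-Hochberg adjusted permutation p = 0.00115 for each). Control replicate 1 is therefore not shown to be the whole of it. A trend with coding length is argued against by a rho of 0.907 in control replicate 1 after the length correction. Genomic DNA in that library stays open: the slope among lower genes was 1.05 times that among higher genes, with a bootstrap 95% interval of 0.769 to 1.42. Copy number of chromosomes in that culture was not tested, and genes on 1 chromosome are not independent.

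The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With a real count of 0 genes all 10 meet it by construction, and the highest other gave 0. For lists, 3 of the 10 gave at least the real 5, and the highest other gave 7, with EPHB replicate 1 grouped with control replicates 1 and 2. For chromosomes, where all 10 again meet the real 0 by construction, the highest other gave 8, with EPHB replicate 1 grouped with control replicates 1 and 3. That split exchanges the pair and keeps the other 4 libraries in their groups, and those 4 alone gave 7.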
